A study of Arabidopsis thaliana with 66 samples.

How the data were processed

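RNA-seq libraries from roots of 4 Arabidopsis genotypes (Col-0 and the stock lines N8507, N8508 and N9416) were analysed, 66 libraries in 22 groups of 3, with genotype and treatment taken from the sample labels. Per the labels, roots had been exposed for 14 days, total RNA had been extracted with a Spectrum Plant Total RNA kit, and libraries had been made with a NEBNext Ultra II Directional kit. Per the submitters' processing notes, reads were trimmed with Trimmomatic and quantified with Salmon 1.3.0 against TAIR10. The deposited tables hold estimated counts of reads per transcript model, which the authors' Salmon run made and which are not normalized. They also hold deposited TPM values from the authors' Salmon run, which were used only in file checks, and effective lengths, used only as a library quality check. Salmon's bias options and the reading of strand are not stated. The 32875 models are coding sequences, since 99.99% of lengths were multiples of 3, so untranslated regions were not counted.

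The estimated counts were summed over the models of each of 27313 genes and rounded. Symbols came from a TAIR10.1 annotation, which matched 26645 genes (97.6%). Since its build name differs from that of the files, it served only for names and for the order of genes. Assigned reads ran from 9.4 M to 16.76 M per library, with a median of 14.83 M in the libraries numbered 128 to 160 (Col-0 and N8507) and 11.99 M in those numbered 193 to 225 (N8508 and N9416). For the latter lines genotype and library series are confounded. No pair of libraries was identical, and the highest correlation of log2 CPM between any pair was 0.9919. The median effective length was low in 3 libraries: Col-0 -P+Th replicate 1 (61.5% of coding length), N8507 -P+Th replicate 3 (56.0%) and N8507 nanoP replicate 3 (57.7%). They were kept, and left out in an alternative.

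Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, two-sided), with TMM normalization, the filterByExpr filter by group and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. Each genotype had a fit of its own with all its groups, so that its groups shared an estimate of the spread, and 19762 (N9416) to 20241 (N8507) genes were tested. Comparisons that cross genotypes used a fit of all 66 libraries with 20839 genes. The common dispersion was 0.0547 in Col-0, 0.0769 in N8507, 0.0214 in N8508 and 0.018 in N9416, so the same count of calls stands for a smaller effect in the latter 2 lines. The SE of a log2 fold change was its absolute value divided by the square root of F. For a gene without a read in a group, the fold change was bounded with a floor of 3 reads over that group.

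There were 35 comparisons planned before the data were examined: -P against mock, nanoP against -P and against mock, -P+Th against -P, nanoP+Th against nanoP and the difference of those thorium effects in each genotype; mock+Th against mock in N8507 and N9416; and each line against Col-0 on mock, in the response to -P and in the thorium effect on -P. A further 3, the thorium effect with nanoP in each line minus that in Col-0, were added after the counts with nanoP had been seen. Overlaps and correlations across genes were computed only for pairs of comparisons with no library in common, and the expected overlap is the product of both counts divided by the genes tested in both.

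The 23 gene lists, with 364 members, had been written from general knowledge before the data were examined. They covered phosphate starvation induced genes, phosphate transport and signalling, iron acquisition, iron sufficiency, sulfur limitation, glutathione transferases and detoxification, oxidative stress, metal transport, aluminium resistance, calcium and touch, nitrate, jasmonate, ethylene, abscisic acid, defence, root hairs, the endodermal barrier, photosynthesis, flavonoids, cell division, DNA damage, heat shock and hypoxia. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, two-sided and adjusted over the 23 lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether a list's genes moved at all. List medians with zero-group genes at their bound are given where they differ from the plain median.

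Named genes followed a rule fixed before the data were examined. From each list with a call came up to 4 members with the largest fold changes, then up to 6 genes that rose most and 6 that fell most with a symbol, at least 5 CPM in the higher group and no overlap between groups. IPS1, SPX1, PHT1;4, PHO1, PHO2, IRT1 and FER1 were always included. The rule was applied to Col-0 and the same genes, or those it gave in a line itself, were named for the lines, with N8507 leading for mock+Th. For comparisons of 4 groups the condition on overlap was not applied. PHT1;1, PHT1;2 and PHT1;3 share reads as near-identical copies, as do SDH3-2 and SDH3-1, and to a lesser degree FRO4 and FRO5, and NRT2.1 and NRT2.2, so their values are uncertain.

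Alternatives were median-of-ratios size factors, no expression filter, DESeq2 1.42.0, a fit of all 66 libraries in place of 1 genotype (or of 2 genotypes in place of all 66), and each library left out in turn. Added after the data had been seen were fits without the 3 libraries of low effective length and without Col-0 -P+Th replicates 2 and 3. Splits of the libraries of the groups compared, 10 for each pair of groups and 100 or 32 draws for differences of effects, gave counts for regroupings that mix the treatments. Libraries carry a running number in the labels and no replicate number, and replicates were numbered by it.

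The procedure was tested on simulated data drawn from the means and library sizes of the real groups, with 100 genes changed at each of 2 sizes. For Col-0 -P+Th against -P, 49% of genes changed by log2 1 and 92% of those changed by log2 2 were recovered with 6 false calls, and for N9416 79% and 97% with 7. For the Col-0 difference of thorium effects by medium the shares were 11% and 74% with 4 false calls. For the thorium effect of N8507 minus Col-0 they were 39% and 88%, with 14 false calls or 9.93% of all calls, above the nominal rate.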

Results

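Roots of 4 Arabidopsis genotypes were compared after 14 days on full medium (mock), phosphate-free medium (-P), phosphate-free medium with nano-hydroxyapatite (nanoP), and each of these with thorium (+Th). The genotypes were Col-0 and the stock lines N8507, N8508 and N9416, whose mutated genes the labels do not name. There were 66 RNA-seq libraries in 22 groups of 3, and mock+Th libraries were part of the N8507 and N9416 sets. Assigned reads per library ranged from 9.4 M to 16.76 M with a median of 13.24 M. The labels do not state whether the 3 replicates of a group came from separate plants or separate plates, so p-values measure only the spread between libraries. Values after gene names are log2 fold changes with their SE, from 3 libraries per group. A value preceded by at least, or at or below, is a bound for a gene without a read in 1 of the groups.

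Some genes were silent in Col-0 and well expressed in every mutant line, or the reverse. Without -P+Th, 45 genes were under 0.5 CPM in all 12 Col-0 libraries and at 5 CPM or more in all 12 of N8508. For 13 it was the reverse. Counts were 46 and 12 for Col-0 with N8507, 46 and 13 with N9416, and at most 2 and 0 between mutant lines. Among these were the lectin-related genes PP2-A6 and PP2-A8 and the resistance-type genes DAR4 and CSA1. All had reads in Col-0 -P+Th and were chosen after values were seen. Every comparison of a mutant line with Col-0 below includes such genes.

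**Figure D1:**
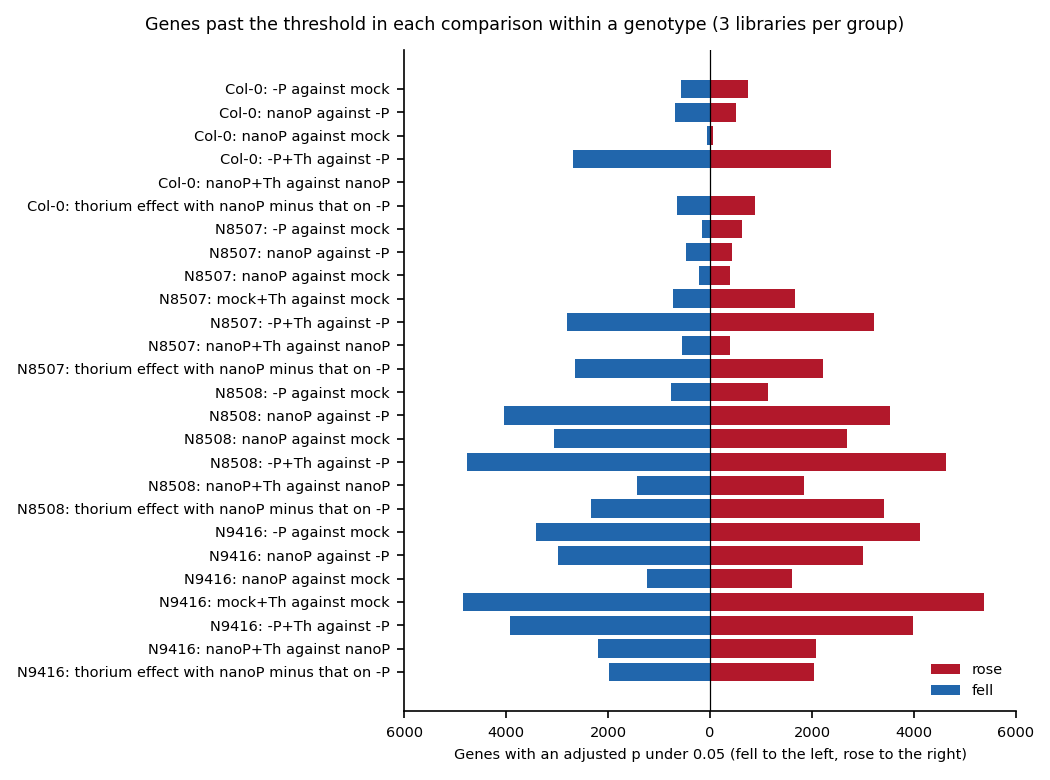
Genes past the threshold in each comparison (horizontal axis, number of genes that rose to the right and fell to the left) for 4 genotypes, n = 3 libraries per group. Thorium with nanoP changed 21 genes in Col-0 and 4287 in N9416.

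The comparison of -P with mock asked how roots responded to the absence of phosphate. In Col-0 roots (3 against 3 libraries) the phosphate starvation genes rose steeply. The non-coding RNA IPS1 (12.07, SE 0.65, adjusted p = 2.3e-08), which sequesters a microRNA, went from 0.172 to 784 CPM. The phosphatase genes PECP1 (10.54, SE 0.64), PS2 (8.62, SE 0.40), PAP24 (at least 5.85) and PAP23 (at least 8.15), the signalling gene SPX1 (5.37, SE 0.47) and the phosphate transporter gene PHT1;4 (7.07, SE 0.28) rose with it. PHO2, which encodes an enzyme that removes phosphate transporters, fell (-1.59, SE 0.27), whereas PHO1 (0.57, SE 0.20, adjusted p = 0.129), needed to load phosphate into the xylem, did not pass. Of the phosphate starvation induced genes 28 rose and 0 fell of 30 (28 and 0 adjusted over the list alone, median 4.11). For the phosphate starvation list this meant camera adjusted p = 1.5e-76 and adjusted p = 3.7e-04 with an estimated correlation. The Col-0 total was 743 genes that rose and 574 that fell, 824 to 1466 in all with 1 library left out.

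Single transporter genes for nitrate, NRT2.5 (-6.13, SE 0.48) and NRT2.2 (-3.97, SE 0.68), ammonium, AMT1;5 (-7.40, SE 0.64), and amino acids, UMAMIT17 (-7.69, SE 0.42), fell in Col-0 on -P, as did the glutamate dehydrogenase gene GDH3 (-7.59, SE 0.31) and the anion channel gene SLAH1 (at or below -7.22). The regulators HHO2 (4.17, SE 0.23) and LBD39 (4.04, SE 0.41), which repress nitrate uptake, rose. More nitrate uptake and assimilation genes rose than fell, 8 rose and 3 fell of 17 (10 and 4 adjusted over the list alone, median 1.01). For the nitrate list this meant camera adjusted p = 1.6e-04 and adjusted p = 0.256 with an estimated correlation. Other genes that fell were the reductase genes FRO4 (-3.59, SE 0.43) and FRO5 (-4.05, SE 0.33), the copper transporter gene COPT2 (-3.91, SE 0.35) and the iron superoxide dismutase gene FSD1 (-2.64, SE 0.43), while the copper-zinc enzyme genes CSD1 (1.1, SE 0.23) and CSD2 (1.21, SE 0.15) rose. CSD1 passed in 5 of 6 fits without 1 library. The metal pump gene HMA2 (4.35, SE 0.26), the nicotianamine synthase gene NAS2 (4.09, SE 0.50) and the barrier gene CASP5 (3.56, SE 0.68) rose.

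Sulfur genes rose moderately in Col-0 on -P, led by the sulfate transporter gene SULTR1;3 (3.83, SE 0.38) and the reductase gene APR2 (2.37, SE 0.22), while the glutathione-degrading gene GGCT2;1 (-3.14, SE 0.84) fell. For sulfur limitation and assimilation genes 6 rose and 1 fell of 17 (10 and 3 adjusted over the list alone, median 0.64). For the sulfur list this meant camera adjusted p = 0.00129 and adjusted p = 0.256 with an estimated correlation. The glutathione transferase genes GSTU22 (-3.36, SE 0.36) and GSTU8 (-2.95, SE 0.40) fell and GSTU20 (1.58, SE 0.30) rose. Of glutathione transferase and xenobiotic detoxification genes (detoxification genes below) 1 rose and 7 fell of 28 (2 and 9 adjusted over the list alone, median -0.08). For the detoxification list this meant camera adjusted p = 0.0281 and adjusted p = 0.866 with an estimated correlation. Calcium transport and touch response genes leaned up (camera adjusted p = 0.0281, adjusted p = 0.674 with an estimated correlation), with CAX3 (1.09, SE 0.16) and TCH3 (0.91, SE 0.24). Root hair genes had 1 of 13 past the threshold, COW1 (1.65, SE 0.42), and 6 and 0 adjusted over the list alone, with camera adjusted p = 0.0281, adjusted p = 0.866 with an estimated correlation. GGCT2;1, TCH3 and COW1 each passed in only 1 of 6 fits without 1 library. The iron transporter gene IRT1 (0.14, SE 0.42, adjusted p = 0.951) and the iron store gene FER1 (0.00, SE 0.16, adjusted p = 1) did not pass.

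The phosphate starvation response differed between the lines. In N8507 IPS1 (6.87, SE 0.54), PECP1 (8.62, SE 0.37) and SPX1 (3.74, SE 0.26) rose and in N9416 IPS1 (10.98, SE 0.49), PECP1 (8.64, SE 0.26) and SPX1 (5.36, SE 0.16) rose. Of the phosphate starvation induced genes 31 of 32 rose in N8507 (median 3.78, camera adjusted p = 1.4e-94, adjusted p = 4.9e-05 with an estimated correlation) and 31 of 32 in N9416 (median 4.43, camera adjusted p = 2.3e-40, adjusted p = 0.0019 with an estimated correlation). In N8508 the same list had 17 rose and 0 fell of 32 (27 and 0 adjusted over the list alone, median 0.63). The phosphate starvation list had camera adjusted p = 1.0e-16 and adjusted p = 0.181 with an estimated correlation. IPS1 in N8508 read 918 CPM on mock and 1264 CPM on -P, a change that did not pass (0.47, SE 0.25, adjusted p = 0.272). The interaction test gave IPS1 (-11.59, SE 0.79, adjusted p = 2.0e-16) for N8508 minus Col-0, PHT1;4 (-5.52, SE 0.32) and SPX1 (-4.91, SE 0.40), and of the list 0 higher and 27 lower of 32 (1 and 29 adjusted over the list alone, median difference -3.30, or -3.14 with zero groups at their bound). In the list test phosphate starvation genes had camera adjusted p = 8.4e-76 and adjusted p = 1.1e-07 with an estimated correlation. For N8507 minus Col-0 the differences were IPS1 (-5.17, SE 0.86), PHT1;4 (-3.43, SE 0.31) and SPX1 (-1.61, SE 0.38) and for the list 6 higher and 15 lower of 32 (6 and 18 adjusted over the list alone, median difference -0.86, or -0.77 with zero groups at their bound). List tests on phosphate starvation genes gave camera adjusted p = 9.2e-05 and adjusted p = 0.514 with an estimated correlation. SPX1 in N8507 minus Col-0 missed the threshold with only the libraries of these 2 genotypes (adjusted p from 9.0e-04 to 0.0741 over all alternatives). For N9416 minus Col-0 IPS1 (-1.07, SE 1.42, adjusted p = 0.776) did not pass. These interactions called 1154 genes in N8507, 1345 in N8508 and 1489 in N9416. With only the 2 genotypes compared the N8507 count was 532.

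Several other groups moved on -P in the mutant lines. Hypoxia response genes fell in N8507, 9 of 12 (1 and 11 adjusted over the list alone, camera adjusted p = 5.1e-13, adjusted p = 0.0448 with an estimated correlation), and in N8508, 5 of 12 (camera adjusted p = 9.3e-06, adjusted p = 0.181 with an estimated correlation). They summed to 8063 CPM (SD 3001) in N8507 on mock against 939.8 to 3753 CPM in its other groups. Photosynthesis genes, markers of green tissue, rose in N8507, 3 of 9 (camera adjusted p = 0.0179, adjusted p = 0.519 with an estimated correlation). Heat shock and protein folding genes fell in N8508, 7 of 12 (camera adjusted p = 1.1e-07, adjusted p = 0.181 with an estimated correlation). In N9416 all 12 jasmonate genes rose (median 2.97, camera adjusted p = 2.4e-09, adjusted p = 0.173 with an estimated correlation) together with 15 of 18 cell division and DNA replication genes (camera adjusted p = 7.8e-07, adjusted p = 0.279 with an estimated correlation). Iron acquisition genes fell in N9416, 14 of 24 (camera adjusted p = 6.9e-04, adjusted p = 0.173 with an estimated correlation). Some falls of Col-0 were shared, those of NRT2.5 (-2.83, SE 0.26), GDH3 (-2.58, SE 0.27) and COPT2 (-4.43, SE 0.22) in N9416 and NRT2.5 (-3.10, SE 0.54) and COPT2 (-2.14, SE 0.47) in N8507, where COPT2 passed in 3 of 6 fits without 1 library.

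Counts on -P were 633 and 157 for N8507, 1140 and 769 for N8508, and 4112 and 3410 for N9416, rose and fell in that order. In 1 fit of all 66 libraries the totals were 1911, 951 and 4157, against 790, 1909 and 7522, and N8507 had 1259 with DESeq2. Col-0 and N9416 shared 508 genes that rose against 151 expected by chance, and their fold changes correlated at r = 0.514 across genes, which are not independent replicates. In all 4 genotypes 101 genes rose and 9 fell, against 0.28 and 0.0288 expected. Values did not overlap between the 2 groups for 26.7% of genes in Col-0, where 10% would occur by chance.

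The comparison of nanoP with -P asked whether the particles acted on roots as a phosphate source. In Col-0 the phosphate starvation genes fell back: IPS1 (-12.62, SE 0.67, adjusted p = 1.9e-08), PECP1 (-11.16, SE 0.67), PS2 (-9.72, SE 0.42), SPX3 (-8.97, SE 0.55), SPX1 (-6.99, SE 0.51) and PHT1;4 (-6.89, SE 0.28). The phosphate transporter gene PHT1;1 (-2.25, SE 0.28) fell and PHO2 (2.55, SE 0.28) rose. Phosphate starvation induced genes counted 0 rose and 29 fell of 30 (0 and 30 adjusted over the list alone, median -4.33). For the phosphate starvation list this meant camera adjusted p = 5.1e-79 and adjusted p = 3.3e-04 with an estimated correlation. In N8507 30 of 32 fell, in N9416 31 of 32, and in N8508 all 32 (median -2.08, camera adjusted p = 2.0e-26, adjusted p = 0.105 with an estimated correlation). IPS1 itself fell in each line: N8507 -7.82 (SE 0.57), N8508 -2.65 (SE 0.26) and N9416 -9.82 (SE 0.44).

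Genes that had fallen on -P rose with nanoP in Col-0. Among them were NRT2.5 (7.50, SE 0.50), NRT2.2 (5.94, SE 0.71), AMT1;5 (8.80, SE 0.63), UMAMIT17 (8.13, SE 0.43), GDH3 (7.42, SE 0.31) and DUR3 (6.27, SE 0.27), the last a urea transporter gene, and FRO5 (3.05, SE 0.32), FRO4 (2.27, SE 0.41) and COPT2 (2.61, SE 0.34). LBD39 (-4.51, SE 0.42), HHO2 (-4.25, SE 0.23), HMA2 (-5.20, SE 0.28) and CASP5 (-3.82, SE 0.70) fell. The sulfur genes SULTR2;1 (-4.08, SE 0.53), SULTR1;3 (-4.04, SE 0.39), LSU2 (-3.06, SE 0.53) and APR2 (-2.96, SE 0.23) fell as well. Of sulfur limitation and assimilation genes 0 rose and 10 fell of 17 (0 and 10 adjusted over the list alone, median -1.61, or -1.50 with zero groups at their bound). The sulfur list had camera adjusted p = 8.1e-11 and adjusted p = 0.014 with an estimated correlation. In N9416 14 of 15 sulfur genes fell (camera adjusted p = 1.7e-12, adjusted p = 0.00732 with an estimated correlation), whereas in N8507 3 rose and 0 fell (camera adjusted p = 0.0052, adjusted p = 0.0376 with an estimated correlation).

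Iron acquisition genes rose with nanoP in Col-0 above their level on either medium. Against -P these were the regulator genes MYB72 (5.94, SE 0.77) and BHLH101 (4.08, SE 0.55), the coumarin gene S8H (4.29, SE 0.36) and the transporter genes IRT2 (5.77, SE 0.60) and IRT1 (2.81, SE 0.44). Against mock they were S8H (6.51, SE 0.44), BHLH101 (4.28, SE 0.56), IRT2 (4.03, SE 0.52), MYB72 (3.62, SE 0.63) and FRO2 (3.47, SE 0.57) and IRT1 (2.95, SE 0.44, adjusted p = 0.00607). Of the iron acquisition genes 13 rose and 1 fell of 26 (18 and 2 adjusted over the list alone, median 1.1) against -P (camera adjusted p = 2.8e-15, adjusted p = 0.024 with an estimated correlation). The list counted 9 rose and 0 fell of 26 (16 and 1 adjusted over the list alone, median 0.78) against mock (camera adjusted p = 3.2e-22, adjusted p = 0.0187 with an estimated correlation). In N8507 11 of 29 rose against -P (camera adjusted p = 6.7e-11, adjusted p = 0.0138 with an estimated correlation) and 9 against mock (camera adjusted p = 3.6e-08, adjusted p = 0.0428 with an estimated correlation). In N9416 10 of 24 rose against -P (camera adjusted p = 0.00566, adjusted p = 0.314 with an estimated correlation), and in N8508 4 rose and 3 fell (camera adjusted p = 0.375). Root hair regulator RSL4 (4.23, SE 0.74) and wall protein PRP1 (3.43, SE 0.85) genes rose in Col-0, while RHD6 (-1.02, SE 0.25) fell. PRP1 passed in 2 of 6 fits without 1 library and RHD6 in 1.

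Single nitrate, sulfate and metal transporter genes also differed between nanoP and mock in Col-0 roots. The nitrate transporter gene NRT2.6 (7.03, SE 0.62) and the zinc transporter gene ZIP8 (3.98, SE 0.68) rose, and the triterpene synthase gene PEN3 (-4.44, SE 0.80) and SULTR2;1 (-3.07, SE 0.53), SULTR1;2 (-1.70, SE 0.27) and GSTU8 (-1.87, SE 0.39) fell. IPS1 (-0.55, SE 1.23, adjusted p = 0.982), SPX1 (-1.62, SE 0.42, adjusted p = 0.151), PHT1;4 (0.18, SE 0.24, adjusted p = 0.981) and PHO2 (0.96, SE 0.27, adjusted p = 0.189) did not pass. SPX1 did with all 66 libraries in 1 fit and with DESeq2 (adjusted p from 3.6e-04 to 0.459 over all alternatives) and PHO2 with DESeq2 (from 0.0319 to 0.517). The genes G3PP1 (-1.62, SE 0.21) and PHT1;8 (-1.23, SE 0.23) fell below mock. ZIP8, PEN3, GSTU8 and PHT1;8, and MYB72 above, passed in none of 6 fits without 1 library, SULTR2;1 in 2, FRO2 in 3 and SULTR1;2 in 5. Flavonoid and anthocyanin genes fell with nanoP in N8507 (3 of 6 against mock, camera adjusted p = 2.1e-05, adjusted p = 0.0483 with an estimated correlation) and against -P in N8508 (4 of 5, camera adjusted p = 0.00264, adjusted p = 0.0977 with an estimated correlation). Heat shock and protein folding genes fell below mock in N8507 (5 of 12) and N8508 (12 of 12). Camera adjusted p was 1.6e-09 and 3.1e-09 (0.0469 and 0.199 with an estimated correlation). N8507 mock stood apart (median 27.1 CPM, other groups at most 9.64). In N8508 phosphate starvation induced genes fell below mock, 30 of 32 (median -1.44, camera adjusted p = 2.9e-20, adjusted p = 0.199 with an estimated correlation), and 20 of 29 detoxification genes fell (camera adjusted p = 3.5e-10, adjusted p = 0.0169 with an estimated correlation).

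Against -P, nanoP changed 1215 genes in Col-0, 908 in N8507, 7566 in N8508 and 5971 in N9416. Against mock the totals, the first of which was 44 to 73 with 1 library left out, were 112, 618, 5752 and 2841 in that order. Without the libraries of low effective length in N8507 (-P+Th replicate 3 and nanoP replicate 3), a setting chosen after the data had been seen, N8507 had 1857 against -P and 2076 against mock. In 1 fit of all 66 libraries the totals against -P were 1867, 2004, 5000 and 2978, and against mock 265, 2129, 3262 and 1088. In all 4 genotypes 216 genes fell and 35 rose against -P, with 0.505 and 0.303 expected. Against mock the changes of N8508 and N9416 correlated at r = -0.0337. In both, 333 genes fell against 192 expected and 154 rose against 216, while 273 and 379 moved in opposite directions against 169.6 and 245. For N8507 and N9416 r was -0.201, and 116 genes rose in N8507 and fell in N9416 against 24.4 expected. Defence genes leaned down against -P in Col-0 (camera adjusted p = 0.00914, adjusted p = 0.0533 with an estimated correlation), with MYB51 (-1.51, SE 0.40) the member past the threshold, in 1 of 6 fits without 1 library.

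**Figure D2:**
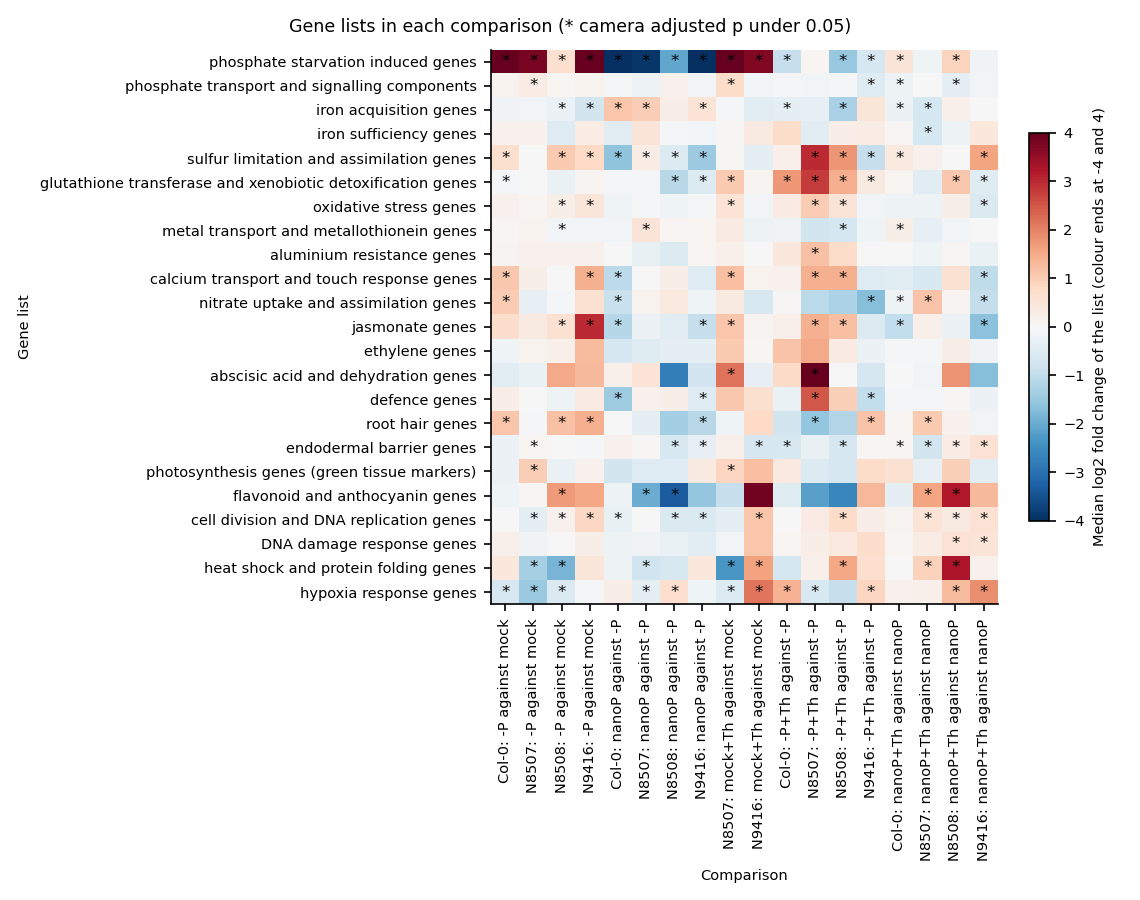
Median log2 fold change of each gene list (rows) in each comparison (columns), red up and blue down, from 3 libraries per group. Marked cells passed the list test, and the phosphate starvation induced genes ran from a median of 4.43 on -P to -5.09 with nanoP in N9416.

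The comparison of mock+Th with mock in N8507 and N9416 asked what thorium did to roots that were given phosphate. It raised phosphate starvation genes in both lines. In N8507 IPS1 (6.83, SE 0.53, adjusted p = 3.3e-07), PECP1 (9.53, SE 0.38), PS2 (7.50, SE 0.44), PHT1;5 (7.28, SE 0.67), SPX1 (4.39, SE 0.27) and PHT1;4 (4.14, SE 0.19) and the zero-group gene PAP14 (at least 6.79) rose. In N9416 IPS1 (10.46, SE 0.49, adjusted p = 8.6e-11), PS2 (8.75, SE 0.53), PECP1 (7.27, SE 0.26), SPX1 (4.76, SE 0.15) and PHT1;4 (4.92, SE 0.27) rose. Phosphate starvation induced genes counted 31 rose and 0 fell of 32 (31 and 0 adjusted over the list alone, median 4.41) in N8507 (camera adjusted p = 3.5e-58, adjusted p = 5.8e-04 with an estimated correlation). They counted 29 rose and 0 fell of 32 (30 and 0 adjusted over the list alone, median 3.71) in N9416 (camera adjusted p = 1.3e-22, adjusted p = 0.0223 with an estimated correlation). PHO2 rose in N8507 (2.34, SE 0.47) and fell in N9416 (-2.53, SE 0.13). Genes that rose here overlapped those that rose on -P without thorium in Col-0: 357 shared with N8507 against 60.8 expected, and 446 with N9416 against 196.

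Single nitrate transporter, reductase and copper transporter genes fell with thorium on full medium. In N8507 these were NRT2.2 (-5.96, SE 1.21), NRT2.4 (-5.62, SE 0.47), NRT2.5 (-5.39, SE 0.63) and NRT2.1 (-4.42, SE 0.48), FRO5 (at or below -8.88) and FRO4 (at or below -8.81) and COPT2 (-4.42, SE 0.58). In N9416 they were NRT2.2 (at or below -8.59), NRT2.5 (-7.17, SE 0.33), NRT2.4 (-3.65, SE 0.51), NRT2.1 (-3.11, SE 0.27), FRO5 (-5.11, SE 0.36) and COPT2 (-4.17, SE 0.22). Nitrate uptake and assimilation genes as a list did not pass in N8507 (5 rose and 7 fell, camera adjusted p = 0.999) or in N9416 (5 rose and 9 fell, camera adjusted p = 0.0979). The malate channel gene ALMT1, a root defence against aluminium, rose in N8507 (2.99, SE 0.45) and in N9416 (6.34, SE 0.71), while aluminium resistance genes as a list did not pass in N8507 (camera adjusted p = 0.164). Detoxification genes rose in N8507, GSTF3 (4.69, SE 0.86), UGT73B4 (4.52, SE 0.61), UGT74E2 (4.1, SE 1.12) and GSTU4 (3.37, SE 0.55) among them, 13 of 29 (camera adjusted p = 1.9e-08, adjusted p = 0.274 with an estimated correlation). UGT74E2 missed the threshold with DESeq2 and passed in 2 of 6 fits without 1 library. In N9416 12 of them rose and 7 fell (camera adjusted p = 0.706).

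The 2 lines parted in their stress groups on mock+Th. The small heat shock genes HSP17.6II (-8.97, SE 1.33), HSP22 (-7.85, SE 1.12) and HSP23.6 (-7.04, SE 1.2) fell in N8507, where 8 of 12 heat shock and protein folding genes fell (camera adjusted p = 4.9e-07, adjusted p = 0.209 with an estimated correlation). The mock libraries stood apart there, with HSP17.6II at 14.9 CPM (SD 15.3), HSP23.6 at 12.3 (SD 14.5) and a list median of 27.1 CPM against 2.34 to 9.64 in the other N8507 groups. In N9416 HSP22 (8.54, SE 1.29), HSP17.6II (8.44, SE 1.21) and HSP23.6 (7.08, SE 1.17) rose and 8 of 12 of the list did (camera adjusted p = 0.0023, adjusted p = 0.405 with an estimated correlation). Hypoxia response genes fell in N8507, 4 of 12 with ADH1 (-1.56, SE 0.46) and SUS1 (-1.15, SE 0.31) (camera adjusted p = 7.2e-04, adjusted p = 0.274 with an estimated correlation), from the same high and variable mock level as on -P. They rose in N9416, 11 of 12 with HRE2 (6.93, SE 0.65), ADH1 (3.90, SE 0.31) and PGB1 (3.05, SE 0.25) (camera adjusted p = 4.3e-06, adjusted p = 0.376 with an estimated correlation). Cell division and DNA replication genes rose in N9416, 17 of 18 with CDKB2;2 (1.78, SE 0.11) and TSO2 (1.29, SE 0.15) (camera adjusted p = 1.5e-06, adjusted p = 0.376 with an estimated correlation). The difference between the lines was not tested in itself. Abscisic acid and dehydration genes rose in N8507, 2 of 4 with RD29A (1.67, SE 0.32) and NCED3 (1.55, SE 0.43) (camera adjusted p = 0.00383, adjusted p = 0.209 with an estimated correlation). In N8507 ADH1 and NCED3 each passed in 2 of 6 fits without 1 library and SUS1 in 3.

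Photosynthesis genes, counted as markers of green tissue in root samples, passed in N8507 with 3 of 9 up, RBCS1A (6.51, SE 1.39) and LHCA4 (2.09, SE 0.40) among them (camera adjusted p = 0.03, adjusted p = 0.342 with an estimated correlation). Ethylene genes did not pass as a list in N8507 (2 rose, camera adjusted p = 0.37) although ERF1 (2.1, SE 0.48) and ACS6 (2.1, SE 0.62) rose. DNA damage response genes had 7 up and 1 down of 12 in N9416 without passing the list test (camera adjusted p = 0.0979), and NAC103 (2.12, SE 0.69), NAC044 (2.05, SE 0.45) and RPA1E (1.2, SE 0.26) rose. Thorium on full medium changed 1663 genes up and 727 down in N8507, and 5376 up and 4838 down in N9416. The N8507 total of 2390 was 4896 in 1 fit of all 66 libraries, where NAC103 missed the threshold. ACS6 passed in none of 6 fits without 1 library, NAC103 in 4 and ERF1 in 5.

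The comparison of -P+Th with -P asked what thorium did without phosphate in the medium, in all 4 genotypes. In Col-0 the malate channel gene ALMT1 (9.35, SE 0.73, adjusted p = 1.5e-06) rose from 0.0851 to 64.5 CPM. It rose in N8507 (8.66, SE 0.53), N8508 (10.47, SE 0.37) and N9416 (8.48, SE 0.58) too. Other large rises in Col-0 were PDF2.1 (7.97, SE 0.68), ALD1 (7.46, SE 1.15), LSU1 (6.64, SE 1.09) and DIN2 (6.21, SE 0.56). Large falls were NRT2.6 (at or below -7.05), GLR2.3 (-8.81, SE 0.86), FRO5 (-7.60, SE 0.55), PIRL8 (-7.05, SE 0.25) and NRT2.5 (-5.38, SE 0.73). Col-0 -P+Th replicates 2 and 3 may be mixed samples (below), which limits Col-0 values on -P+Th. Aluminium resistance genes counted 1 of 5 up in Col-0 and 3 of 5 in N8507 (camera adjusted p = 0.0115, adjusted p = 0.085 with an estimated correlation).

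The phosphate transport genes PHO1 and PHT1;2 fell with thorium on -P in all 4 genotypes. PHO1 fell by 1.04 (SE 0.20) in Col-0, 3.01 (SE 0.35) in N8507, 2.38 (SE 0.14) in N8508 and 1.3 (SE 0.09) in N9416. The uptake transporter gene PHT1;2 (-4.01, SE 0.28) fell in Col-0, with -5.87 in N8507, -8.60 in N8508 and -2.2 in N9416, and PHT1;1 (-2.73, SE 0.29) and PHT1;8 (-1.98, SE 0.23) fell as well. PHT1;1 and PHT1;2 are near-identical copies that share reads, so the values of each alone are uncertain. Many of the phosphate starvation induced genes fell in Col-0, PECP1 (-2.44, SE 0.41), MGD3 (-2.06, SE 0.25), IPS1 (-1.66, SE 0.37) and PHT1;4 (-1.14, SE 0.22) included. The list counted 0 rose and 20 fell of 30 (1 and 20 adjusted over the list alone, median -0.93). The phosphate starvation list had camera adjusted p = 6.9e-09 and adjusted p = 0.314 with an estimated correlation. 29 of 32 fell in N8508 (camera adjusted p = 1.0e-13, adjusted p = 0.314 with an estimated correlation) and 20 of 32 in N9416 (camera adjusted p = 8.6e-06, adjusted p = 0.318 with an estimated correlation). N8507 had 8 up and 7 down (camera adjusted p = 0.716). N8507 minus Col-0 differed for 19 higher and 2 lower of 32 (22 and 2 adjusted over the list alone, median difference 1.12). In the list test phosphate starvation genes had camera adjusted p = 6.3e-08 and adjusted p = 0.138 with an estimated correlation. Among phosphate transport and signalling components WRKY75 (4.00, SE 0.46) rose in Col-0, where the list did not pass (camera adjusted p = 0.663), and the list passed in N9416 with 8 of 15 down (camera adjusted p = 0.016, adjusted p = 0.126 with an estimated correlation).

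Detoxification genes rose with thorium on -P. In Col-0 the glutathione transferase genes GSTU3 (4.68, SE 0.94), GSTU8 (4.35, SE 0.43) and GSTU22 (3.86, SE 0.37) and the glucosyltransferase gene UGT73B4 (4.05, SE 0.35) rose, the last also in N8507 (5.76), N8508 (5.07) and N9416 (2.08). Of detoxification genes 23 of 28 rose in Col-0 (camera adjusted p = 1.7e-14, adjusted p = 0.219 with an estimated correlation) and 27 of 29 in N8507 (camera adjusted p = 2.7e-18, adjusted p = 0.085 with an estimated correlation). The list rose for 22 of 29 in N8508 (camera adjusted p = 9.8e-10, adjusted p = 0.0199 with an estimated correlation) and 10 of 28 in N9416 (camera adjusted p = 0.016, adjusted p = 0.385 with an estimated correlation). Oxidative stress genes included AOX1D (4.35, SE 0.60) and UPOX (1.85, SE 0.60) in Col-0, and as a list passed in N8507 (9 rose and 2 fell of 21, camera adjusted p = 0.00365, adjusted p = 0.174 with an estimated correlation). Hypoxia response genes rose in Col-0, HRE2 (4.07, SE 0.95), PDC1 (2.82, SE 0.55) and PGB1 (2.72, SE 0.40) with them, 8 of 12 (camera adjusted p = 1.2e-05, adjusted p = 0.355 with an estimated correlation). UPOX missed the threshold without replicates 2 and 3 of Col-0 -P+Th and passed in 3 of 6 fits without 1 library. Hypoxia response genes were lower in the thorium effect of N8507 than in that of Col-0 for 10 of 12 (camera adjusted p = 6.3e-09, adjusted p = 0.0729 with an estimated correlation) and in N8508 for 9 (camera adjusted p = 1.6e-09, adjusted p = 0.104 with an estimated correlation).

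Single genes of iron, copper and nitrate uptake fell in Col-0 under thorium on -P. They included the coumarin gene S8H (-4.75, SE 0.73), the reductase gene FRO2 (-3.93, SE 0.63), the transporter gene IRT1 (-2.25, SE 0.45) and the regulator gene FIT (-1.82, SE 0.30). The reductase gene FRO4 (-4.79, SE 0.70), the copper transporter gene COPT2 (-3.90, SE 0.59) and the nitrate genes NRT2.2 (at or below -3.85), NRT2.4 (-4.57, SE 0.47) and NRT2.1 (-4.51, SE 0.53) fell too, while nitrate uptake and assimilation genes as a list did not pass (1 rose and 7 fell, camera adjusted p = 0.188). NRT2.2 missed the threshold without the 3 libraries of low effective length or without replicates 2 and 3 of Col-0 -P+Th, and passed in 1 of 6 fits without 1 library. The vacuolar metal pump gene HMA3 (-3.88, SE 0.39) fell and the iron store gene FER1 (0.96, SE 0.16) rose. IRT1 fell in N8507 (-4.08, SE 0.49) and N8508 (-8.00, SE 1.08) but rose in N9416 (1.84, SE 0.55). The N9416 rise missed the threshold without -P+Th replicate 1 or -P replicate 2, where it was 1.5 in each. N9416 minus Col-0 was 4.01 (SE 0.77, adjusted p = 1.7e-04). Iron acquisition genes fell in Col-0 (8 of 26, camera adjusted p = 0.0207, adjusted p = 0.455 with an estimated correlation) and in N8508 (17 of 23, camera adjusted p = 2.4e-04, adjusted p = 0.386 with an estimated correlation), whereas 9 rose and 3 fell in N9416 (camera adjusted p = 0.0641). Iron sufficiency genes counted 3 up and 1 down of 8 in Col-0 (camera adjusted p = 0.108). In N9416 15 of 17 nitrate uptake and assimilation genes fell (camera adjusted p = 3.7e-08, adjusted p = 0.126 with an estimated correlation). Metal transport and metallothionein genes fell as a list in N8508 (10 of 23, camera adjusted p = 0.0254, adjusted p = 0.314 with an estimated correlation).

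Sulfur genes separated the lines under thorium on -P. Sulfur limitation and assimilation genes rose in N8507, 13 of 17 (camera adjusted p = 1.3e-10, adjusted p = 2.1e-04 with an estimated correlation), and N8508, 13 (camera adjusted p = 1.8e-06, adjusted p = 0.269 with an estimated correlation). They fell in N9416, 10 of 15 (camera adjusted p = 1.1e-04, adjusted p = 0.153 with an estimated correlation). In Col-0 LSU1 (6.64, SE 1.09), GGCT2;1 (3.37, SE 0.84) and SULTR2;1 (1.85, SE 0.42) rose and SULTR1;1 (-3.21, SE 0.54) fell. SULTR2;1 missed the threshold without replicates 2 and 3 of Col-0 -P+Th (0.98), a setting chosen after the data had been seen, and GGCT2;1 passed in 5 of 6 fits without 1 library. The difference from Col-0 was SULTR2;1 (7.83, SE 0.69), SDI1 (5.90, SE 0.51) and BGLU28 (at least 5.53) for N8507, and for the list 11 higher and 1 lower of 17 (12 and 1 adjusted over the list alone, median difference 2.38). In the list test sulfur genes had camera adjusted p = 1.0e-13 and adjusted p = 9.1e-05 with an estimated correlation. BGLU28 missed the threshold with DESeq2. For N8508 the list was 8 higher and 1 lower of 17 (9 and 1 adjusted over the list alone, median difference 1.05), camera adjusted p = 1.8e-08, adjusted p = 0.00467 with an estimated correlation, and for N9416 1 higher and 11 lower of 17 (1 and 13 adjusted over the list alone, median difference -1.01). List tests on sulfur genes gave camera adjusted p = 2.4e-07 and adjusted p = 0.00967 with an estimated correlation.

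Root barrier genes fell with thorium on -P in Col-0, the Casparian strip gene CASP4 (-1.95, SE 0.29) and the suberin genes FAR1 (-1.37, SE 0.17) and GPAT5 (-0.87, SE 0.13) among them. Endodermal barrier genes counted 0 rose and 8 fell of 18 (0 and 11 adjusted over the list alone, median -0.63). For the barrier list this meant camera adjusted p = 3.3e-05 and adjusted p = 0.314 with an estimated correlation. In N8508 11 of 17 fell (camera adjusted p = 0.00518, adjusted p = 0.415 with an estimated correlation). Root hair genes fell in N8507, 9 of 13 (camera adjusted p = 0.0115, adjusted p = 0.535 with an estimated correlation), and rose in N9416, 8 of 13 (camera adjusted p = 0.00322, adjusted p = 0.497 with an estimated correlation). In Col-0 PRP1 (5.56, SE 0.85) and RSL4 (3.12, SE 0.74) rose and LRX1 (-2.01, SE 0.57) and PRX73 (-1.90, SE 0.51) fell. LRX1 missed the threshold without the 3 libraries of low effective length, and PRX73 without replicates 2 and 3 of Col-0 -P+Th. In fits without 1 library they passed in 3 and 5 of 6. Jasmonate genes rose in N8507 and N8508 (8 and 9 of 12, camera adjusted p = 0.00229, adjusted p = 0.332 with an estimated correlation, and for N8508 camera adjusted p = 0.00195, adjusted p = 0.314 with an estimated correlation). Defence genes rose in N8507 (4 of 9, camera adjusted p = 0.00229, adjusted p = 0.129 with an estimated correlation) and fell in N9416 (5 of 10, camera adjusted p = 0.0204, adjusted p = 0.384 with an estimated correlation). Cell division and DNA replication genes rose in N8508, 14 of 18 (camera adjusted p = 3.7e-05, adjusted p = 0.314 with an estimated correlation).

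Thorium on -P changed 2374 genes up and 2693 down in Col-0, 3225 and 2813 in N8507, 4627 and 4766 in N8508, and 3981 and 3931 in N9416. The Col-0 total of 5067 was 3313 to 6372 with 1 library left out, and 9286 without replicates 2 and 3 of Col-0 -P+Th, where the lone library left was assumed to vary like the other groups. In 1 fit of all 66 libraries N8507 went from 6038 to 9164 and N9416 from 7912 to 4938. In all 4 genotypes 301 rose and 408 fell, with 16.7 and 17.9 expected. Fold changes correlated at r = 0.607 between Col-0 and N8508 but at r = 0.0628 between N8507 and N9416, which shared 604 risen genes against 619 expected and 715 fallen genes against 552, while 756 and 681 moved in opposite directions against 612 and 559. The thorium effect differed from that of Col-0 for 4261 genes in N8507, 3087 in N8508 and 3923 in N9416. The N8507 count was 2607 with only the 2 genotypes compared, and without the 2 Col-0 libraries N8508 had 7223 and N9416 7072. Some large differences, PP2-A6 (at or below -6.55) and DAR4 (at or below -5.98) in N8507, came from genes whose Col-0 reads all stood in replicates 2 and 3 of -P+Th. The thorium effects on full medium and on -P, which share no libraries, correlated at r = 0.611 in N9416 (2860 rose in both against 1083 expected) and r = 0.429 in N8507 (853 against 265).

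**Figure D3:**
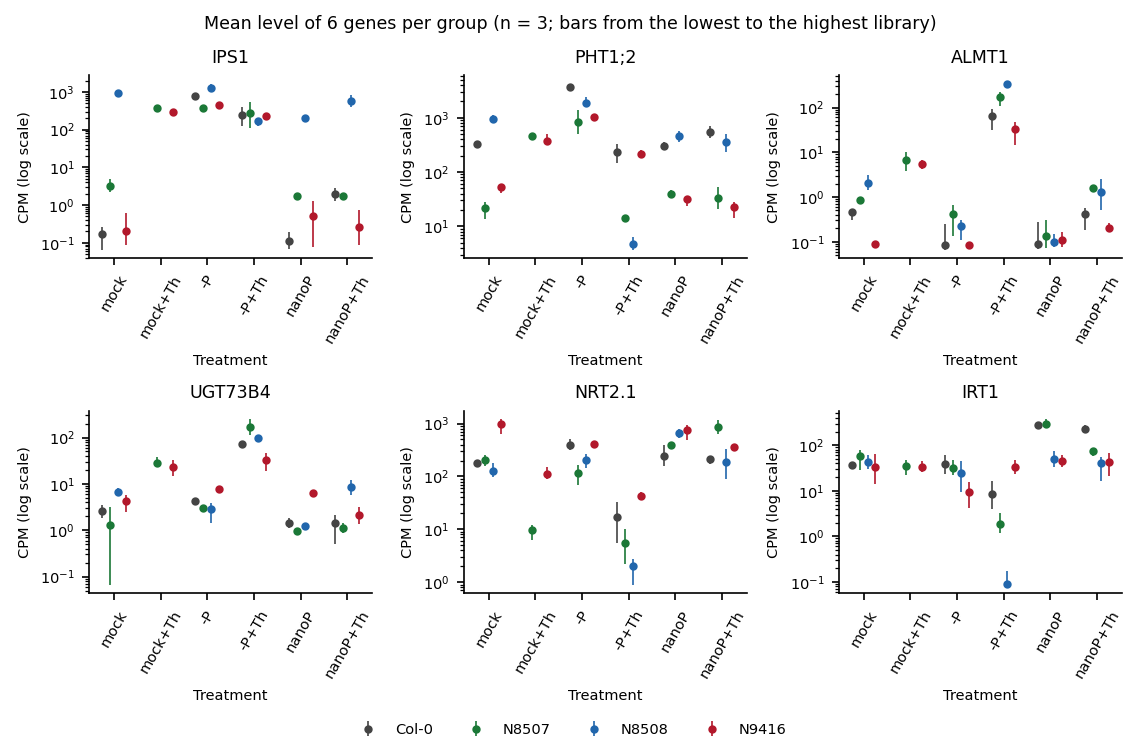
Mean CPM (log axis) of 6 genes in each treatment, coloured by genotype, with bars from the lowest to the highest of 3 libraries and values under a floor of 3 reads over the group drawn at that floor. ALMT1 stood at 64.5 CPM on -P+Th and at 0.0851 CPM on -P in Col-0.

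The comparison of nanoP+Th with nanoP asked how much of the thorium effect remained when particles were present. In Col-0 16 genes rose and 5 fell. The metal pump gene HMA2 (3.01, SE 0.28, adjusted p = 4.5e-04), the kinase gene CIPK9 (2.33, SE 0.28), the potassium transporter gene HAK5 (1.76, SE 0.23), the exchanger gene CHX17 (1.78, SE 0.29), the sulfate transporter gene SULTR1;2 (1.51, SE 0.27) and the glycerol phosphate transporter gene G3PP1 (1.93, SE 0.22) rose. The nitrate transporter genes NRT1.8 (-3.17, SE 0.43) and NRT2.6 (-2.71, SE 0.44) and FAF3 (-1.27, SE 0.21) and PIRL8 (-1.04, SE 0.17) fell. With 1 library left out, 5 to 12 genes passed. HMA2, CIPK9 and G3PP1 passed in each of these 6 fits, CHX17, SULTR1;2, NRT2.6 and PIRL8 in none, FAF3 in 1, NRT1.8 in 4 and HAK5 in 5. The total was 107 with all 66 libraries in 1 fit and 150 with DESeq2. IPS1 (3.97, SE 0.80, adjusted p = 0.102), SPX1 (1.65, SE 0.42, adjusted p = 0.254), PHO1 (-0.12, SE 0.20, adjusted p = 1) and IRT1 (-0.27, SE 0.41, adjusted p = 1) did not pass. IPS1 and SPX1 did pass with all 66 libraries in 1 fit and with DESeq2, and over all alternatives their adjusted p ranged from 7.2e-05 to 0.473 and from 7.2e-04 to 0.885. Phosphate starvation induced genes as a list passed upward (1 past the threshold, 12 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 7.7e-18, adjusted p = 0.0486 with an estimated correlation). So did metal transport and metallothionein genes (1 past the threshold, 8 and 0 adjusted over the list alone, camera adjusted p = 3.0e-07, adjusted p = 0.0486 with an estimated correlation).

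The mutant lines changed more. In N8508 the small heat shock genes HSP23.6 (8.70, SE 1.15) and HSP17.4 (8.17, SE 1.04) and the zero-group genes HSP17.6II (at least 8.52) and HSP22 (at least 7.67) rose, with 11 of 12 heat shock and protein folding genes (camera adjusted p = 5.4e-14, adjusted p = 0.0514 with an estimated correlation). Detoxification genes rose there, 17 of 29 with UGT73B4 (2.76, SE 0.32) and GSTU24 (2.32, SE 0.31) (camera adjusted p = 1.4e-08, adjusted p = 0.0339 with an estimated correlation). ALMT1 rose there (3.55, SE 0.72), and so did 22 of 32 phosphate starvation induced genes, IPS1 (1.57, SE 0.26) and PHT1;4 (1.40, SE 0.16) included (camera adjusted p = 4.4e-14, adjusted p = 0.181 with an estimated correlation). In N9416 hypoxia response genes rose, 11 of 12 with HRA1 (3.75, SE 0.45), PDC1 (3.06, SE 0.57) and HRE2 (2.82, SE 0.58) (camera adjusted p = 1.9e-09, adjusted p = 0.121 with an estimated correlation). There 9 of 12 jasmonate genes fell with LOX3 (-3.5, SE 0.68) and JAZ10 (-2.74, SE 0.47) (camera adjusted p = 5.0e-08, adjusted p = 0.121 with an estimated correlation). Sulfur limitation and assimilation genes rose in N9416, 11 of 15 with SDI1 (3.35, SE 0.49) and SULTR2;1 (2.27, SE 0.51) (camera adjusted p = 1.5e-08, adjusted p = 0.0634 with an estimated correlation). In N8507 the suberin genes GPAT5 (-2.44, SE 0.24), KCS2 (-2.42, SE 0.20), CYP86B1 (-2.42, SE 0.25) and CYP86A1 (-2.18, SE 0.21) and the iron genes IRT2 (-4.13, SE 0.72), MYB72 (-4.1, SE 0.72) and IRT1 (-1.92, SE 0.41) fell and the nitrate reductase gene NIA1 (2.93, SE 0.28) rose. Endodermal barrier genes fell in N8507, 8 of 18 (camera adjusted p = 7.6e-06, 0.05 with an estimated correlation). They rose in N9416, 13 of 17 (camera adjusted p = 2.2e-06, 0.163 with an estimated correlation). Summed CPM in N9416 with nanoP, nanoP+Th and mock was 2511, 811 and 980 for jasmonate genes. It was 880, 1356 and 1377 for sulfur and 1542, 2014 and 1936 for barrier genes, so these ended near mock. Hypoxia genes (1326, 4925 and 1440) did not. DNA damage response genes rose in N8508 (3 of 12, camera adjusted p = 0.0179, adjusted p = 0.0804 with an estimated correlation) with NAC044 (2.23, SE 0.40) and BRCA1 (0.57, SE 0.17). BRCA1 missed the threshold with all 66 libraries in 1 fit and passed in 1 of 6 fits without 1 library, and IRT1 in N8507 in 4.

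Totals were 942 in N8507, 3265 in N8508 and 4287 in N9416. This order was not kept with all 66 libraries in 1 fit, where they were 2793, 1294 and 1691. The fold changes of the lines correlated with those of Col-0 at r = 0.13, 0.159 and 0.257. In all 4 genotypes 1 gene rose and 1 fell. Comparisons of the thorium effect with nanoP between each line and Col-0, added after these counts had been seen, called 803 genes in N8507, 263 in N8508 and 409 in N9416. The N8507 count was 384 with only the 2 genotypes compared and 1279 without the 3 libraries of low effective length, and N8508 had 401 with DESeq2. In N8507 minus Col-0 these included IPS1 (-3.91, SE 1.1), NRT2.5 (-7.26, SE 0.74), GPAT5 (-2.96, SE 0.24) and NIA1 (3.31, SE 0.34), of which IPS1 passed in 6 of 12 fits without 1 library.

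The difference between the thorium effect with nanoP and that on -P was tested directly in each genotype. In Col-0 the thorium effect was lower with nanoP for ALMT1 (-7.29, SE 2.07, adjusted p = 0.0444) and for SLAH1 (at or below -6.54), PDF2.1 (-6.97, SE 0.94), AOX1D (-5.02, SE 0.95), WRKY75 (-4.89, SE 0.63), UGT73B4 (-4.04, SE 0.53) and GSTU8 (-3.96, SE 0.55). With 1 library left out, ALMT1 ranged from -10.82 to -3.70 and missed the threshold in 6 of 12 fits. It was higher with nanoP for FRO5 (8.70, SE 0.64), FRO4 (5.87, SE 0.81), COPT2 (5.07, SE 0.66), NRT2.5 (4.88, SE 0.87), NRT2.4 (4.66, SE 0.59), PHT1;2 (4.85, SE 0.37), PHT1;1 (3.31, SE 0.39) and CASP4 (1.94, SE 0.40). PHO1 (0.92, SE 0.28, adjusted p = 0.0626) did not pass, though it did in 6 of 18 alternatives. These were DESeq2, the fits without the 3 libraries of low effective length (0.68), without replicates 2 and 3 of Col-0 -P+Th (1.58) and without each of its 3 replicates. Over all alternatives its adjusted p ranged from 1.9e-04 to 0.125. Detoxification genes were 0 higher and 13 lower of 28 (0 and 18 adjusted over the list alone, median difference -2.01). The detoxification list had camera adjusted p = 4.9e-14 and adjusted p = 0.127 with an estimated correlation. Phosphate starvation induced genes were 19 higher and 0 lower of 30 (22 and 0 adjusted over the list alone, median difference 1.70), camera adjusted p = 1.3e-16, adjusted p = 0.12 with an estimated correlation, and endodermal barrier genes 8 higher and 0 lower of 18 (9 and 0 adjusted over the list alone, median difference 0.78). The barrier list had camera adjusted p = 1.7e-07 and adjusted p = 0.21 with an estimated correlation. ALMT1 differed in N8507 (-5.26, SE 1.25), N8508 (-6.91, SE 1.75) and N9416 (-7.55, SE 1.95) as well, passing in 11, 11 and 10 of 12 fits without 1 library, and PHO1 in N8507 (2.99, SE 0.47), N8508 (1.69, SE 0.19) and N9416 (1.91, SE 0.12).

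The detoxification list was lower in the nanoP effect in each line too: 25 of 29 in N8507 (camera adjusted p = 1.4e-16, adjusted p = 0.0943 with an estimated correlation). The counts were 11 of 29 in N8508 (camera adjusted p = 0.00197, adjusted p = 0.151 with an estimated correlation) and 12 of 28 in N9416 (camera adjusted p = 7.1e-06, adjusted p = 0.142 with an estimated correlation). Sulfur limitation and assimilation genes differed downward in N8507 (10 of 17, camera adjusted p = 9.4e-08, adjusted p = 0.00104 with an estimated correlation) and upward in N9416 (12 of 15, camera adjusted p = 1.1e-12, adjusted p = 0.0125 with an estimated correlation). This interaction called 1538 genes in Col-0, 4866 in N8507, 5741 in N8508 and 4022 in N9416. The Col-0 count was 7463 without replicates 2 and 3 of Col-0 -P+Th, 2518 with DESeq2 and 1000 to 2795 with 1 library left out. In 1 fit of all 66 libraries the 4 counts were 2592, 8011, 3689 and 1733. In simulation, with 100 genes changed per size, Col-0 recovery was 11% at log2 1 and 74% at log2 2. Small real differences may go unseen.

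The comparison of each line with Col-0 on mock asked how the genotypes differed without treatment. PHO2 was far lower in N8507, 54.7 against 1118 CPM (-4.35, SE 0.34, adjusted p = 5.6e-15). IPS1 was higher in N8507 (4.15, SE 0.76) and in N8508 (12.28, SE 0.70), and PHT1;4 (5.14, SE 0.25) and SPX1 (5.46, SE 0.32) were higher in N8508. In N8508 30 of 32 phosphate starvation induced genes were above Col-0 (median 4.23, camera adjusted p = 2.8e-49, adjusted p = 1.4e-05 with an estimated correlation). In N9416 IPS1 (0.24, SE 1.3, adjusted p = 0.914) did not pass. Its nitrate uptake and assimilation genes were higher for 13 of 17 (camera adjusted p = 1.6e-07, adjusted p = 0.0556 with an estimated correlation), and cell division and DNA replication genes were lower for 15 of 18 (camera adjusted p = 1.4e-06, adjusted p = 0.314 with an estimated correlation). In N8507 detoxification genes were lower for 20 of 29 (camera adjusted p = 1.4e-06, adjusted p = 0.833 with an estimated correlation) and hypoxia response genes, variable on mock, higher for 9 of 12 (camera adjusted p = 1.3e-04, adjusted p = 0.833 with an estimated correlation). Totals were 7526, 5663 and 6635 for N8507, N8508 and N9416. Some large differences, DAR4 (at least 10.15) and PP2-A6 (at least 9.96) in N8507, were in genes silent in Col-0. Genotype is confounded with library series in N8508 and N9416. A series effect common to both would not raise phosphate starvation induced genes in N8508 alone, where they summed to 13294 CPM (SD 1325) on mock, against 693 (SD 6.09) in N9416 and 1047 (SD 60.4) in Col-0.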

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

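The tests of the first and second patterns below and the comparisons of the thorium effect with nanoP between genotypes were chosen after the results had been seen.

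In Col-0 outside -P+Th, 34 genes were silent that N8508 and N9416 expressed, and 10 showed the reverse, 44 genes chosen without N8507 libraries. A difference between library series does not account for them, since N8507 libraries carry numbers in the Col-0 range, yet 0 of the 44 genes had the Col-0 state in N8507, and 41 had that of the other lines. A strain variant against the reference remains open, since 4 pairs of these genes were neighbours in the reference gene order, against at most 3 in 10000 random sets. A candidate explanation is that the libraries labelled Col-0 came from a strain other than the reference, as 77.6% of the genes silent in 1 of Col-0 and N8508 and expressed in the other were silent in Col-0. An effect of the mutated genes, shared by the 3 lines, was not tested.

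Reads of 32 genes silent in the other Col-0 libraries appeared in libraries labelled Col-0 -P+Th, at 3 reads or more for 5 genes in replicate 1, 28 in replicate 2 and 32 in replicate 3. The median level in replicate 3 was 9.24% of that in the -P+Th libraries of the other lines, which argues against a mislabelled sample. A mixed sample may account for replicates 2 and 3, since 87.5% of the genes in replicate 3 lay within 2-fold of that median share. Thorium switching the genes on cannot be told apart from it, with 15.6% of the genes at 3 reads or more in replicate 1. Without replicates 2 and 3 the count for thorium on -P in Col-0 was 9286 against 5067, resting on replicate 1, which had a low effective length (61.5%) and was assumed to vary like the other groups.

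Thorium with nanoP changed 21 genes in Col-0 and 4287 in N9416, and the difference between these effects passed for 409 genes. A difference in spread between libraries does not explain the gap as a whole, since with all 66 libraries in 1 fit the counts were 107 and 1691, or 6.33%. Library size does not either, as the Col-0 libraries held 1.22 times the assigned reads. With 1 library left out, counts ranged from 5 to 12 in Col-0 and from 2736 to 4317 in N9416. N8507, numbered with Col-0, had 942 (2793 in 1 fit), which argues against library series alone. The genotype, confounded with it in N9416, stays open.

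Differences between groups, tested directly, drew attention to the following counts. The thorium effect with nanoP differed from that on -P for 1538 genes in Col-0 (5 of 100 splits gave as many, highest other 2253), 4866 genes in N8507 (1 of 100 splits gave as many, highest other 3623), 5741 genes in N8508 (3 of 100 splits gave as many, highest other 8469) and 4022 genes in N9416 (4 of 100 splits gave as many, highest other 8270). The splits regroup treated and untreated libraries within each medium. These shares do not decide on chance, since splits that keep or turn round the real contrast of a medium hold real changes. Of the 99 other splits 77, chosen after the results were seen, kept neither contrast. Their highest counts were 80, 0, 0 and 0 in that order.

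The response to -P differed from that in Col-0 for 1154 genes in N8507 (4 of 32 splits gave as many, highest other 1553), 1345 genes in N8508 (1 of 32 splits gave as many, highest other 910) and 1489 genes in N9416 (4 of 32 splits gave as many, highest other 3249). The thorium effect on -P differed from that in Col-0 for 4261 genes in N8507 (7 of 32 splits gave as many, highest other 7780), 3087 genes in N8508 (5 of 32 splits gave as many, highest other 5445) and 3923 genes in N9416 (3 of 32 splits gave as many, highest other 4712). The thorium effect with nanoP differed from that in Col-0 for 803 genes in N8507 (4 of 32 splits gave as many, highest other 2318), 263 genes in N8508 (5 of 32 splits gave as many, highest other 702) and 409 genes in N9416 (5 of 32 splits gave as many, highest other 1523). Nor do these shares decide on chance, for the same reason. The 21 of 31 other splits keeping neither contrast gave at most 676, 1 and 0 for the response to -P. They gave at most 2675, 39 and 28 for the thorium effect on -P and 3, 1 and 1 with nanoP. Here and above, mixed treatments widen the spread, so low counts do not decide. Each difference from Col-0 is confounded with the library series in N8508 and N9416, and with the silent genes above in all 3 lines.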

How the results depend on the processing

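Leaving out the 3 libraries of low effective length, leaving out replicates 2 and 3 of Col-0 -P+Th, and comparing the thorium effect with nanoP between genotypes were chosen after the data had been seen, and the other alternatives before the data were examined. Of 474 counts of genes recomputed under alternatives, 393 lay within 1.5 times the reported count, and 8 of the 38 counts did so under every alternative run. With DESeq2 size factors in edgeR, and without the filter on low counts, all 38 counts did. Of 3495 recomputed values of named genes, 3290 had the reported direction and side of the threshold, 180 lost the call, 14 gained one and 11 changed sign. The direction and side of the threshold held for 250 of 310 named results under every alternative run.

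With all 66 libraries in 1 fit, 22 of 26 counts within genotypes moved by more than 1.5 times. They rose in Col-0 from 1215 to 1867 for nanoP against -P, from 112 to 265 for nanoP against mock, from 21 to 107 for nanoP+Th against nanoP and from 1538 to 2592 for the thorium effect with nanoP minus that on -P. In N8507 they rose from 790 to 1911 for -P against mock, from 908 to 2004 for nanoP against -P, from 618 to 2129 for nanoP against mock and from 2390 to 4896 for mock+Th against mock. They rose there too from 6038 to 9164 for -P+Th against -P, from 942 to 2793 for nanoP+Th against nanoP and from 4866 to 8011 for the thorium effect with nanoP minus that on -P. They fell in N8508 from 1909 to 951 for -P against mock, from 7566 to 5000 for nanoP against -P, from 5752 to 3262 for nanoP against mock, from 3265 to 1294 for nanoP+Th against nanoP and from 5741 to 3689 for the thorium effect with nanoP minus that on -P. In N9416 they fell from 7522 to 4157 for -P against mock, from 5971 to 2978 for nanoP against -P, from 2841 to 1088 for nanoP against mock, from 7912 to 4938 for -P+Th against -P, from 4287 to 1691 for nanoP+Th against nanoP and from 4022 to 1733 for the thorium effect with nanoP minus that on -P. This fit gives all genotypes the same spread, with a coefficient of variation of 0.208, against 0.234 in Col-0, 0.277 in N8507, 0.146 in N8508 and 0.134 in N9416 fitted apart. With DESeq2 the counts moved in Col-0 from 112 to 351 for nanoP against mock, from 21 to 150 for nanoP+Th against nanoP and from 1538 to 2518 for the thorium effect with nanoP minus that on -P. With DESeq2 they also moved in N8507 from 790 to 1259 for -P against mock, from 908 to 1493 for nanoP against -P, from 618 to 1376 for nanoP against mock and from 942 to 1721 for nanoP+Th against nanoP, and in N8508 minus Col-0 from 263 to 401 for the thorium effect with nanoP. With only the libraries of the 2 genotypes compared, N8507 minus Col-0 moved from 1154 to 532 for the response to -P, from 4261 to 2607 for the thorium effect on -P and from 803 to 384 for the thorium effect with nanoP. Without the 3 libraries of low effective length, the counts moved in N8507 from 908 to 1857 for nanoP against -P, from 618 to 2076 for nanoP against mock and from 942 to 1874 for nanoP+Th against nanoP, and in N8507 minus Col-0 from 803 to 1279 for the thorium effect with nanoP. Without replicates 2 and 3 of Col-0 -P+Th, the lone library left, of low effective length, was assumed to vary like the other groups. The counts then moved in Col-0 from 5067 to 9286 for -P+Th against -P and from 1538 to 7463 for the thorium effect with nanoP minus that on -P. In N8508 minus Col-0 the count moved from 3087 to 7223 for the thorium effect on -P, and in N9416 minus Col-0 from 3923 to 7072 for the thorium effect on -P. Of 874 list tests, 308 passed with the fixed correlation, 46 with an estimated one, 520 by fry in mixed directions and 379 in 1. Of the 308, 248 passed the mixed fry test, 246 the other and 43 every test. None changed direction. The cause of these moves in the counts was not tested.

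With 1 library left out, 40 of 306 counts moved by more than 1.5 times, where the alternative itself holds fewer libraries. In Col-0 the lowest and highest were 824 (without mock replicate 3) to 1466 for -P against mock, 44 (without mock replicate 3) to 73 for nanoP against mock, 3313 (without -P replicate 2) to 6372 for -P+Th against -P, 5 (without nanoP+Th replicate 2) to 12 for nanoP+Th against nanoP and 1000 (without -P replicate 2) to 2795 for the thorium effect with nanoP minus that on -P. In N8507 the lowest and highest were 434 (without -P replicate 3) to 752 for -P against mock, 578 (without -P replicate 2) to 802 for nanoP against -P, 383 (without mock replicate 1) to 568 for nanoP against mock, 1478 (without mock+Th replicate 3) to 2353 for mock+Th against mock and 440 (without nanoP+Th replicate 2) to 1005 for nanoP+Th against nanoP. In N8508 the lowest and highest were 1031 (without mock replicate 1) to 1875 for -P against mock and 1737 (without nanoP replicate 3) to 3379 for nanoP+Th against nanoP. In N9416 the lowest and highest were 1709 (without mock replicate 2) to 2696 for nanoP against mock and 2736 (without nanoP replicate 3) to 4317 for nanoP+Th against nanoP. In N8508 minus Col-0 the lowest and highest were 1840 (without Col-0 -P+Th replicate 1) to 4382 for the thorium effect on -P and 157 (without N8508 nanoP replicate 3) to 234 for the thorium effect with nanoP. In N9416 minus Col-0 the lowest and highest were 2595 (without Col-0 -P replicate 1) to 5180 for the thorium effect on -P.

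No named gene with a call changed sign in any alternative. FER1 in Col-0 on -P read -0.0099 with DESeq2 size factors in edgeR, -0.0103 in 1 fit of all 66 libraries and -0.00997 with DESeq2. Genes without a call whose sign changed with 1 library left out ranged from -0.19 to 0.11 for FER1 in Col-0, -P against mock, -0.33 to 0.41 for IRT1 in Col-0, -P against mock, -0.16 to 0.41 for PHT1;4 in Col-0, nanoP against mock, -0.23 to 0.0244 for PHO1 in Col-0, nanoP+Th against nanoP, -4.29 to 0.84 for IPS1 in N9416 against Col-0 on mock and -1.67 to 3.46 for IPS1 in N9416 minus Col-0, response to -P. In Col-0, named genes that lost their call in at least 1 of these fits were COW1, CSD1, GGCT2;1 and TCH3 (-P against mock), MYB51, PRP1 and RHD6 (nanoP against -P) and FRO2, GSTU8, MYB72, PEN3, PHT1;8, SULTR1;2, SULTR2;1 and ZIP8 (nanoP against mock). The others in Col-0 were GGCT2;1, LRX1, NRT2.2, PRX73 and UPOX (-P+Th against -P), CHX17, FAF3, HAK5, NRT1.8, NRT2.6, PIRL8 and SULTR1;2 (nanoP+Th against nanoP) and ALMT1 and AOX1D (the thorium effect with nanoP minus that on -P). In N8507 they were COPT2 (-P against mock), ACS6, ADH1, ERF1, NCED3, SUS1 and UGT74E2 (mock+Th against mock), IRT1 (nanoP+Th against nanoP) and ALMT1 (the thorium effect with nanoP minus that on -P). In N8508 they were BRCA1 (nanoP+Th against nanoP) and ALMT1 (the thorium effect with nanoP minus that on -P). In N9416 they were NAC103 (mock+Th against mock), IRT1 (-P+Th against -P) and ALMT1 (the thorium effect with nanoP minus that on -P). In N8507 minus Col-0 they were BGLU28 (the thorium effect on -P) and IPS1 (the thorium effect with nanoP). Of simulated 2-fold changes, 49% were recovered for thorium on -P in Col-0 and 79% in N9416. For the thorium effect with nanoP minus that on -P in Col-0, it was 11%. These shares may not hold where more genes change, or for genes with few reads.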

Other observations

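The counts over splits below were planned before the data were examined. Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. The real split was the highest, at 1 of 10, in 25 of 25. Splits here mix treatments or genotypes, which widens the spread, so low counts of the others do not decide. Real counts left out are given above. In Col-0 the real count and the highest other were 1317 and 0 for -P against mock, 1215 and 435 for nanoP against -P, 112 and 0 for nanoP against mock, 5067 and 1 for -P+Th against -P and 21 and 0 for nanoP+Th against nanoP. In N8507 the highest other was 7 for nanoP against mock and 0 otherwise. In N8508 the highest other was 0 in each. In N9416 the highest other was 0 in each. On mock against Col-0 the real count and highest other were 7526 and 5 for N8507, 5663 and 0 for N8508 and 6635 and 0 for N9416.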
